A study of Mus musculus with 60 samples.

How the data were processed

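Gene expression was measured in the cortex of male mice of 30 inbred strains that received either plain water or fluoxetine, an antidepressant that blocks the reuptake of serotonin. Per the labels, fluoxetine was given orally at 18 mg/kg per day (0 mg/kg in the water group) for 21 days, and RNA of 3 mice of the same strain and treatment was pooled for each array. The set held 60 Affymetrix expression arrays, 1 per strain and treatment, which gave 30 arrays in each group. No separate cultures or animals were measured one by one. The p-values reflect how far the difference between both arrays of a strain varied over strains. That spread mixes differences of response between strains, differences between pools and technical spread. Scan dates and hybridisation batches were not given in the sources used here and could not be entered as batches.

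The values deposited by the authors were linear intensities, 1 per probe set and array, computed with GCRMA per the submitters' processing notes, with the version not given in the sources used here. GCRMA corrects probe intensities for background by probe sequence, normalizes between arrays and summarizes the probes of a probe set. That the scale was linear was read from the values themselves, which ran from 4.21 to 72333.5, and they were transformed to log2 without a pseudocount. The lowest value, 2.07 on the log2 scale, was shared by 26.0% to 27.9% of probe sets on each array, so it was treated as a floor below which no level was resolved. The background correction compresses values near that floor, and differences between low values there have no order.

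Of 45101 probe sets, 34945 were paired with 1 gene name in the platform annotation, 932 with several, 9160 with none, and 64 were controls. Probe sets with several names were not used for any gene. A gene was represented by its probe set with the highest mean log2 intensity over the 60 arrays, which gave 18193 genes. The Entrez numbers of 18032 of them were found in the mouse gene name table used here, and 0 symbols changed. No genome build was named in the sources used here, so no coordinates are printed. A gene was tested if its log2 intensity was at least 4 in at least 6 arrays, a rule that does not use the groups, and 11886 genes passed.

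Every choice of test, filter, gene list and rule for naming genes was fixed before the data were examined, apart from the additions stated as such in the results and the closing part. Fluoxetine and water were compared with limma (lmFit and eBayes), with strain as a block and Benjamini-Hochberg adjustment at 0.05, two-sided. Differences are given as fluoxetine minus water on the log2 scale. The strain block came from the strain label, since each strain gave 1 water and 1 fluoxetine array. The pairing was checked: the fluoxetine array of 30 of 30 strains correlated best with the water array of its own strain, and the reverse held for 30 of 30, with correlations of the deviations from the group means of 0.519 to 0.855. Without the block, the fit gave 0 genes where the paired fit gave 7.

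Differences between strains were tested with the F-test of the strain coefficients in the same fit, and the intraclass correlation of both arrays of a strain was computed after removal of the treatment means. With 1 array per strain and treatment, a strain-specific response has no replicate. Strains of shared ancestry therefore served as replicates: 16 strains were assigned from textbook genealogy to 4 families (129S1/SvImJ with BTBRT T(+) tf/J and LP/J, then the Bagg albino-derived, the C57/C58-related and the Swiss-derived strains), and their within-strain differences were compared with a limma F-test. Similarity of responses was the Pearson correlation across genes of the centred within-strain differences, tested by permuting strain labels 100000 times, one-sided. A Mantel permutation test with as many permutations, one-sided, set the similarity of responses against the similarity of mean expression over all 30 strains.

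Gene lists fixed in advance covered transmitter systems, growth factors, immediate early genes, stress response, clock, synapse, metabolism, protein folding and immune genes, and markers of the cell types of the cortex and of neighbouring tissue. Of 37 lists, the 34 with at least 5 measured members were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. The calls were also computed with an estimated correlation, with fry, and with a sign-flip permutation of the list means over the 30 strains. Several lists share members, such as Gad1 in the lists of interneuron markers and of GABA synthesis.

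Genes were named by rule: the 12 with the largest rise and the 12 with the largest fall among those past the threshold, or all of them where fewer passed; a fixed set of serotonin, neurotrophic, glucocorticoid and activity genes; the 4 members with the smallest p of each list past its test; the 12 genes with the largest standard deviation of strain means and all measured members of a list of genes known to vary between strains; and the 8 genes with the smallest p between families. Any other gene named was chosen after its values were seen, except that members of fixed lists are named as examples of those lists.

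The tests were run on simulated data first. With 50 of 11886 genes changed at each fold size in the comparison of fluoxetine and water, 35 were called at 1.1-fold, 47 at 1.2-fold, 48 at 1.5-fold and 50 at 2-fold, with 10 false calls. In simulated strain differences, 190 of 200 changed genes were called with 13 false calls, and in simulated family differences 126 of 200 with 3 false calls. A shifted list was called and 0 other lists were. The simulations drew residuals independently for each gene, and the real arrays share structure between genes.

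Alternatives covered the strain block, subtraction of array medians, quantile normalization, no filter or a filter at log2 6, the mean of all probe sets of a gene, every probe set on its own, marker scores (oligodendrocyte, striatum, choroid plexus and red blood cell) as covariates, the 3' minus 5' signal of the Actb and Gapdh controls as covariates, trended and robust variance, array weights, a Wilcoxon signed-rank test per gene (strains with a difference of 0 dropped), each strain left out in turn, Spearman correlation, only the genes with the largest residual spread and removal of the first component of the responses. The red blood cell score rested on 1 measured gene. No array was left out. Depth does not apply to arrays, and their number limits the precision. R 4.3.3 with limma 3.58.1 was used for the statistics and Python 3.11.15 with matplotlib 3.10.9 for the figures.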

Results

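Cortical expression was measured in 30 inbred mouse strains, each represented by 1 array of water-treated males and 1 array of males given fluoxetine for 21 days. The design asks which cortical genes change with chronic antidepressant treatment on many genetic backgrounds, how far expression differs between the strains, and whether the response follows ancestry. Each array carried RNA pooled from 3 mice. The median intensity of an array lay between 39.1 and 43.1, and arrays correlated with each other at 0.966 to 0.997 over genes. Quality measures were close between the treatments: the 3' minus 5' signal of Actb differed by -0.0015 (SD 0.112, n = 30 strains; permutation p = 0.942) and that of Gapdh by -0.0004 (SD 0.0611; permutation p = 0.972), on the log2 scale. The spike-in controls differed by -0.02 (SD 0.265; permutation p = 0.703).

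With chronic fluoxetine 7 of 11886 genes passed the threshold in the cortex, 2 of them higher and 5 lower. Tfrc, the transferrin receptor through which cells take up iron, fell by 0.13 on the log2 scale (SE 0.0229; lower in 25 of 30 strains; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0224), a change of -8.81%. Ciart, a repressor within the circadian clock, fell by 0.39 (SE 0.0776; lower in 24 of 30; limma adjusted p = 0.0308), a change of -23.9%. Gnb4, a beta subunit of heterotrimeric G proteins, fell by 0.16 (SE 0.0294; lower in 27 of 30; limma adjusted p = 0.0288). The adaptor protein gene Sh3d19 fell by 0.19 (SE 0.0365; lower in 25 of 30; limma adjusted p = 0.0308), and the zinc finger gene Zfp945 fell by 0.29 (SE 0.0551; lower in 27 of 30; limma adjusted p = 0.0308). Spata13 rose by 0.44 (SE 0.0872; higher in 23 of 30; limma adjusted p = 0.0351), a change of 35.2%. Nefh, the heavy chain of neurofilaments in large axons, rose by 0.12 (SE 0.0233; higher in 25 of 30; limma adjusted p = 0.0308).

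Over all genes the median absolute difference was 0.03, and 195 genes had a limma adjusted p under 0.1, of which 86 were higher and 109 lower. At an unadjusted p under 0.05 there were 1819 genes, 868 higher and 951 lower, against a mean of 594 expected if no gene differed. Genes share structure over strains, so the number that arises by chance can lie far from 594. It was not counted with swapped labels, so this excess is not a test. Other probe sets of the called genes had differences of the same sign, such as -0.13 and -0.14 for Gnb4 and -0.27 for Tfrc (SD 0.750, lower in 19 of 30 strains). Several were smaller: that of Sh3d19 was -0.04 with 13 strains lower and 13 higher, and those of Zfp945 were -0.10 and -0.06. Those of Spata13 were 0.13 and 0.10, each higher in 16 strains, against 0.44 for the probe set used. The probe set used for Zfp945 had a strain mean under 6 in 9 strains, the lowest at 2.52, near the floor where values are compressed. Its largest fall, -0.99, was in 129S1/SvImJ, which is among these strains. Over strains, the other probe sets of Zfp945 correlated with the one used at -0.864 to -0.154. The count of 7 rested on the composition of the strain panel. It was 0 without C57BLKS/J or without C58/J, 1 (Tfrc) without C57BL/6J, C57BR/cdJ, DBA/2J or MA/MyJ, 2 without SWR/J, 3 without NZW/LacJ or NZB/BlNJ, 4 without AKR/J, CE/J, CBA/J or NOD/LtJ, 12 without BTBRT T(+) tf/J and 21 without RIIIS/J. Tfrc passed in 28 of these 30 fits. The call was lost for all 7 genes with the mean of all probe sets of a gene or with marker scores as covariates, and without a filter on low values only Tfrc passed. Over 13 alternatives the difference kept its size for Nefh (0.11 to 0.13), Tfrc (-0.15 to -0.11) and Gnb4 (-0.16 to -0.12), and it ranged from 0.22 to 0.44 for Spata13, from -0.40 to -0.26 for Ciart, from -0.31 to -0.15 for Zfp945 and from -0.19 to -0.06 for Sh3d19. Some of these settings, such as no block or another filter, return the same difference by construction, so they do not test its size.

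**Figure D1:**
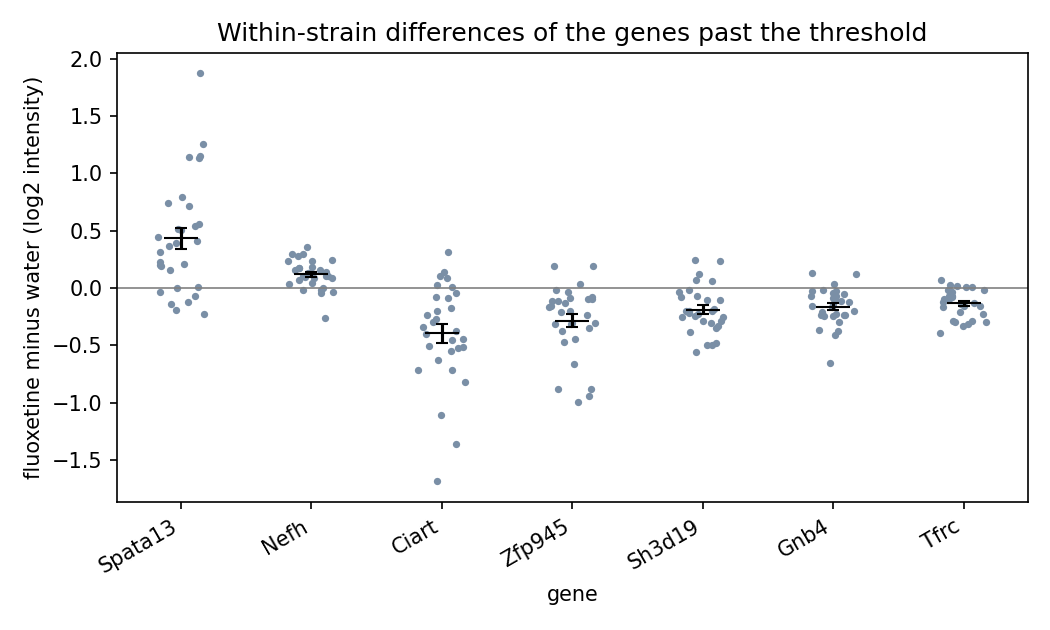
Difference in log2 intensity, fluoxetine minus water, of the 7 genes past the threshold. Each point is 1 of 30 strains, the horizontal bar is the mean and the error bar its standard error; Ciart and Spata13 spread most over strains and Tfrc and Nefh least.

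The serotonin system, the direct target of the drug, had no measured member past the threshold. Slc6a4, the serotonin transporter that fluoxetine blocks, and Tph2, the enzyme that makes serotonin in neurons, lay at the floor of 2.07 and 2.08 and were not tested. Both are transcribed mainly in raphe neurons of the brainstem. No probe set was paired with Htr2a alone. Among the receptors, Htr1a differed by -0.13 (SE 0.0655; lower in 21 of 30; limma adjusted p = 0.345), Htr1b by -0.06 (limma adjusted p = 0.640, lower in 16), Htr2c by -0.05 (limma adjusted p = 0.508, lower in 16) and Htr3a by -0.09 (limma adjusted p = 0.443, lower in 19). Maoa, which degrades serotonin, differed by 0.03 (limma adjusted p = 0.640, higher in 18), and S100a10, a partner of serotonin receptors, by 0.05 (limma adjusted p = 0.688, higher in 16).

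Genes often followed in antidepressant studies did not pass in the paired fit either. Bdnf, the brain-derived neurotrophic factor, differed by 0.33 with a standard error of 0.126 (limma adjusted p = 0.204), and it was higher in 15 strains and lower in 15. In settings chosen after the data were seen, Bdnf differed by 0.06 without the 5 strains of largest response. It passed with the first component of the responses as a covariate (limma adjusted p = 0.00015). However, this covariate is computed from the same arrays, in genes outside the fixed lists. The same fit called up to 904 genes with treatment labels swapped within strains. Its receptor gene Ntrk2 differed by -0.01 (limma adjusted p = 0.823, lower in 21), and Fkbp5, a glucocorticoid-induced chaperone, by 0.08 (limma adjusted p = 0.402, higher in 19). The activity-regulated genes Fos, Arc and Egr1 differed by 0.03 (limma adjusted p = 0.957, higher in 14), 0.10 (limma adjusted p = 0.755, higher in 21) and 0.0041 (limma adjusted p = 0.988, higher in 15).

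As groups, 7 of 34 tested gene lists passed camera at its preset correlation, 5 of them lower and 2 higher with fluoxetine. With treatment labels swapped within strains, 19 of 100 splits, the real one included, called as many lists, with a median of 4. The oligodendrocyte markers, genes of the myelin-forming cells, fell as a group, with 11 of 11 measured members lower, a median of -0.22 and a lower list mean in 20 of 30 strains (camera adjusted p = 1.74e-08). The adjusted p = 0.375 with an estimated correlation, since these members move together (estimated correlation 0.818). Adjusted over the list alone 8 members fell, and 0 passed over all genes tested. Mal and Opalin, which encode myelin proteins, differed by -0.29 (limma adjusted p = 0.0764, lower in 22) and -0.27 (limma adjusted p = 0.102, lower in 21). Aspa, the enzyme that splits N-acetylaspartate, and Cldn11, a tight junction protein of myelin, both differed by -0.22 (limma adjusted p = 0.0904, lower in 22, and 0.0963, lower in 24). The oligodendrocyte precursor markers fell too, with 8 of 8 members lower, a median of -0.08 and a lower mean in 21 strains (camera adjusted p = 0.000734). Their adjusted p = 0.375 with an estimated correlation. Adjusted over the list alone 3 members fell and over all genes 0, and the growth factor receptor gene Pdgfra differed by -0.12 (limma adjusted p = 0.0764, lower in 23). The lineage factors Olig1 and Olig2 differed by -0.09 (limma adjusted p = 0.0963, lower in 23) and -0.08 (limma adjusted p = 0.208, lower in 19), and Lhfpl3 by -0.08 (limma adjusted p = 0.363, lower in 18). With marker scores as covariates, which hold the oligodendrocyte score itself, the calls for the list oligodendrocyte (camera adjusted p = 0.879) and the list oligodendrocyte precursor (0.125) were lost.

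Circadian clock genes fell as a group, with 12 of 17 lower, a median of -0.07 and a lower mean in 23 of 30 strains (camera adjusted p = 0.000734). The adjusted p = 0.375 with an estimated correlation. Adjusted over the list alone 6 members fell, and over all genes only Ciart did. The clock output factor Dbp differed by -0.27 (limma adjusted p = 0.0764, lower in 25), the repressor Nr1d2 by -0.11 (limma adjusted p = 0.0807, lower in 23) and Per1 by -0.14 (limma adjusted p = 0.118, lower in 21). The call for the list circadian clock was lost without the 5 strains of largest response, an omission chosen after the data were seen, with a median of -0.0094 and a camera adjusted p = 0.0572. Genes of cholesterol synthesis fell as a group, with 16 of 20 lower, a median of -0.06 and a lower mean in 26 of 30 strains (camera adjusted p = 6.28e-05). Their adjusted p = 0.488 with an estimated correlation. Adjusted over the list alone 6 members fell and over all genes 0. Lss and Fdft1, enzymes at the start of the sterol branch, differed by -0.13 (limma adjusted p = 0.0764, lower in 26) and -0.09 (limma adjusted p = 0.116, lower in 24), Insig1, which restrains the sterol-sensing pathway, by -0.12 (limma adjusted p = 0.101, lower in 23) and the demethylase Cyp51 by -0.09 (limma adjusted p = 0.135, lower in 24).

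Genes of the heat shock and unfolded protein response rose as a group, with 22 of 28 higher, a median of 0.04 and a higher mean in 22 of 30 strains (camera adjusted p = 6.82e-05). The adjusted p = 0.375 with an estimated correlation. There were 3 members that rose when adjusted over the list alone and 0 over all genes. The chaperone gene Hsph1 differed by 0.11 (limma adjusted p = 0.0836, higher in 25) and Hspa1b by 0.29 (limma adjusted p = 0.0836, higher in 21), with the reservation that Hspa1b has a near-identical copy, Hspa1a. Atf6, a sensor of the endoplasmic reticulum, differed by 0.07 (limma adjusted p = 0.132, higher in 20), as did the disulfide isomerase gene Pdia6 (limma adjusted p = 0.213, higher in 22). Lysosomal genes rose slightly, with 20 of 28 higher, a median of 0.02 and a higher mean in 19 of 30 strains (camera adjusted p = 0.00827). The adjusted p = 0.546 with an estimated correlation, and adjusted over the list alone 0 members passed, as over all genes. The call for the list lysosome was lost without the same 5 strains (median 0.01, camera adjusted p = 0.149), with the mean of all probe sets of a gene (0.0785) and with marker scores as covariates (0.0648). The smallest p among them were those of the hydrolases Gusb (0.14, limma adjusted p = 0.180, higher in 21), Man2b1 (0.10, limma adjusted p = 0.183, higher in 17), Lipa (0.12, limma adjusted p = 0.204, higher in 21) and Hexa (0.07, limma adjusted p = 0.206, higher in 19).

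Endothelial markers fell, with 9 of 11 lower, a median of -0.04 and a lower mean in 18 of 30 strains (camera adjusted p = 0.0404). The adjusted p = 0.546 with an estimated correlation. A single member (1) fell when adjusted over the list alone and 0 over all genes. The transporter gene Slco1a4 differed by -0.10 (limma adjusted p = 0.0904, lower in 21), the receptors Tek and Flt1 by -0.11 (limma adjusted p = 0.204, lower in 21) and -0.10 (limma adjusted p = 0.205, lower in 20), and the efflux pump gene Abcb1a by -0.06 (limma adjusted p = 0.477, lower in 16). The call for the list endothelium was lost when any of 12 strains was left out, with a camera adjusted p between 0.0503 without A/J and 0.127 without RIIIS/J; the others were 129S1/SvImJ, C57BL/6J, C57BLKS/J, C3H/HeJ, FVB/NJ, NZW/LacJ, PL/J, AKR/J, MA/MyJ and CBA/J. It was also lost without the block (0.0699), with a filter at log2 6 (0.0645), with the mean of all probe sets (0.0747) and with the first component as a covariate (0.0639). The median difference stayed between -0.06 and -0.03 over the 14 alternatives, some of which, such as fry, reuse the same differences. With an estimated correlation 0 of 34 lists passed camera, fry called 1 (the oligodendrocyte precursor markers, adjusted p = 0.0188), and the sign-flip permutation of list means, chosen after the data were seen, called 4: circadian clock (adjusted p = 0.0034), heat shock (0.0262), oligodendrocyte precursor (0.0262) and oligodendrocyte (0.0341).

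**Figure D2:**
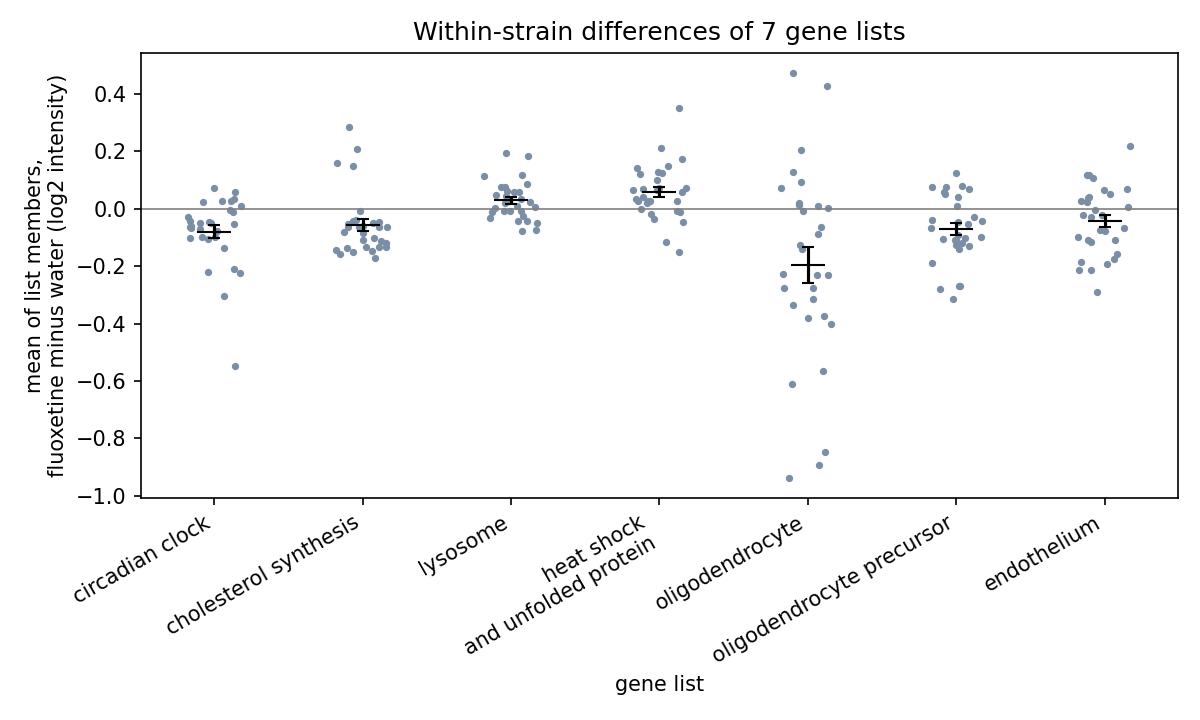
Mean difference in log2 intensity, fluoxetine minus water, over the members of each of the 7 gene lists that passed camera at its preset correlation. Each point is 1 of 30 strains, the horizontal bar is the mean and the error bar its standard error; the oligodendrocyte list spreads most over strains.

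The other 27 lists did not pass. The serotonin system had a median of -0.05 over 11 measured members, 8 of them lower (camera adjusted p = 0.357). Its list mean was lower in 20 of 30 strains, short of the threshold with fry (adjusted p = 0.0641) and the sign-flip permutation (adjusted p = 0.0564). The neurotrophin and growth factor list had a median of 0.01 (camera adjusted p = 0.195), with Vgf (0.13), Nrn1 (0.07) and Creb1 (0.05) higher when adjusted over the list alone. Among neuropeptides and interneuron markers (median -0.02, adjusted p = 0.671) the members went both ways. Adjusted over the list alone 5 fell, namely Penk (-0.29), Tac1 (-0.13), Sst (-0.11), Vip (-0.09) and Pvalb (-0.07), and 3 rose, namely Nos1 (0.23), Pdyn (0.14) and Cck (0.08), and over all genes 0 passed. Medians were 0.0041 for immediate early genes (adjusted p = 0.945), -0.0036 for the glucocorticoid response (0.883), 0.02 for the catecholamine system (0.389), 0.02 for glutamate receptors and transporters (0.555), -0.02 for GABA synthesis, transport and receptors (0.671), 0.0021 for synaptic vesicle genes (0.671), -0.0053 for the postsynaptic density (0.555) and -0.0023 for cAMP signalling (0.671). They were -0.0067 for oxidative phosphorylation (0.431), 0.0012 for ribosomal proteins (0.426), -0.02 for the interferon response and MHC class I (0.932), -0.0074 for extracellular matrix and perineuronal nets (0.389) and 0.0029 for strain-variable reference genes (0.435).

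Among the cell type and region markers, medians were -0.03 for upper-layer neurons (camera adjusted p = 0.357), -0.03 for deep-layer neurons (0.751), -0.0053 for GABA interneurons (0.671), 0.02 for astrocytes (0.389), 0.04 for microglia (0.105), -0.04 for pericytes and smooth muscle (0.671) and -0.04 for meninges (0.787). They were -0.04 for striatum (0.405), -0.0062 for hippocampus (0.671), -0.04 for thalamus (0.431) and 0.06 for olfactory bulb and neuroblasts (0.389). Too few members were measured for a test of choroid plexus (2 genes, median -0.36), red blood cells (1 gene, -0.03) and hypothalamus (2 genes, 0.05). Between 1 and 3 members passed when adjusted over the list alone in the glucocorticoid, synaptic vesicle, postsynaptic density, cAMP, extracellular matrix, GABA interneuron, striatum and olfactory bulb lists, and 0 of them over all genes. The sign of the median and that of the test differed for the interferon, cAMP and extracellular matrix lists, whose tests pointed upward, and the mean of the synaptic vesicle list was -0.0001 against its positive median and test.

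Strains differed widely. Of 11886 genes, 10500 (88.3%) passed the limma F-test between strains after Benjamini-Hochberg adjustment and 1386 did not. The median intraclass correlation of both arrays of a strain was 0.593, and it was over 0.9 for 675 genes. A processing batch shared by both arrays of a strain would raise this correlation and the F-test count. On the first principal component of the arrays, most arrays of strains deposited up to C58/J lay on one side. Most arrays of the strains deposited later lay on the other side. Along that axis, batch and strain cannot be told apart. For 779 of the genes that passed, the strain means spanned at least 2 log2 units. Galc, the lysosomal galactosylceramidase of myelin turnover, reached 9.52 in CE/J (SD of strain means 3.27) and lay under 6 in 12 strains. Rpn1, a subunit of the oligosaccharyltransferase, lay under 6 in only CE/J and P/J (SD 2.31), and Tmem87a lay under 6 in 6 strains and reached 10.19 in SJL/J (SD 2.70). Baiap2l1 reached 6 in 5 strains (SD 2.45), Gdpd3 in 7 (SD 2.63) and 4930578G10Rik in 8 (SD 2.27). The largest SD was 4.27, for Gm13306, which reached 14.07 in BUB/BnJ, and the other genes in this group of 12 were Zfp945 (2.72), Rbm45 (2.46), AI506816 (2.45), Stk25 (2.29) and Tmem267 (2.29). Low strain means near the floor of the values have no order, so that these SDs do not measure the full range of transcript level and do not rank the genes. A variant under the probes can lower a probe set without a change of transcript level. Over strains, other probe sets correlated with the one used at 0.999 for Baiap2l1, at -0.853 for Galc, at -0.864 to -0.154 for Zfp945 and at -0.287 to 0.999 for Rpn1.

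All 11 measured genes of the list known to vary between strains passed the same F-test, with the largest limma adjusted p, 0.00473, for Ide. Since 88.3% of all genes passed this test, these passes do not set the list apart. Gabra2, a subunit of the GABA receptor, was lowest in C57BL/6J at 9.91. Glo1, which detoxifies methylglyoxal, ranged from 11.26 in LG/J to 13.79 in A/J, with its other probe sets correlated at 0.656 to 0.910. Alad, an enzyme of heme synthesis, ranged from 9.03 in SM/J to 11.43 in C57BR/cdJ, and its other probe set correlated at 0.962. Nnt, a mitochondrial transhydrogenase, ranged from 9.48 in CE/J to 10.81 in BALB/cJ, and Cd59a, a complement inhibitor, from 5.85 in BTBRT T(+) tf/J to 10.00 in SWR/J. The class I histocompatibility genes ranged from 4.76 in C58/J to 11.50 in P/J for H2-K1 and from 6.58 in AKR/J to 12.16 in P/J for H2-D1, whose other probe sets correlated at -0.824 to 0.944. H2-Ea ranged from 7.63 in SWR/J to 9.04 in MRL/MpJ, Ttc13 from 10.48 in LG/J to 11.43 in BALB/cJ and Btbd9 from 8.85 in RIIIS/J to 9.88 in A/J. Other probe sets correlated over strains with the one used at only 0.00226 to 0.468 for Ttc13 and at -0.423 to 0.700 for Ide, against 0.889 for Cd59a and 0.650 for Nnt.

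**Figure D3:**
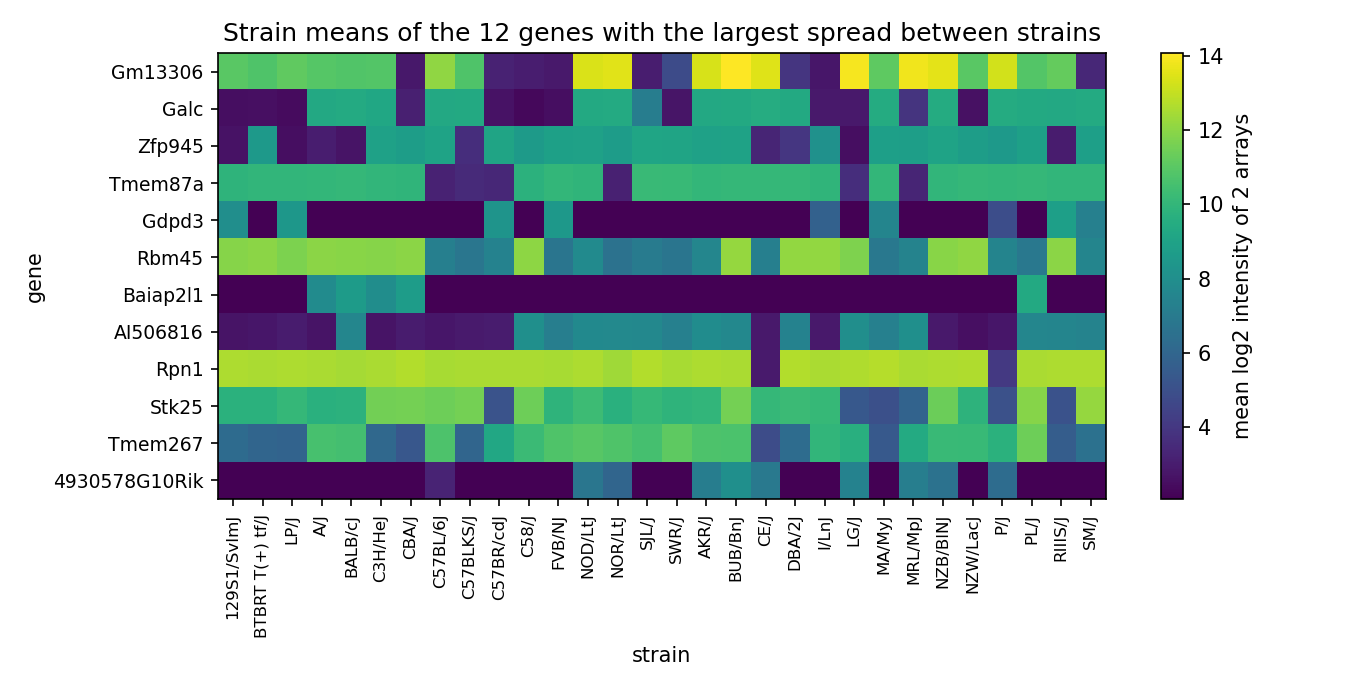
Mean log2 intensity of both arrays of a strain (colour) for the 12 genes with the largest spread between strains (vertical) in 30 strains (horizontal). Rpn1 is low in CE/J and P/J only, and Baiap2l1 reaches 6 in 5 strains.

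The response to fluoxetine was compared between the 4 strain families, which asks whether related genetic backgrounds respond alike. No gene passed: the limma F-test over 16 strains called 0 genes after Benjamini-Hochberg adjustment, with 729 at an unadjusted p under 0.05 and a smallest adjusted p of 0.735. The 8 genes with the smallest p, all at a limma adjusted p of 0.735, are given as values. Prodh, the proline dehydrogenase, differed by -0.31 in C57/C58-related strains (0 of 4 higher) and by 0.12 in Bagg albino-derived strains (4 of 4 higher). Pnmt, which makes adrenaline, differed by 0.17 (4 of 4 higher) and -0.24 (0 of 4 higher) in the same families. Apaf1, a scaffold of the apoptosome, differed by 0.44 in C57/C58-related strains (4 of 4 higher), Tigd2 by 0.30 (4 of 4 higher), Tmem164 by -0.34 (0 of 4 higher) and the phosphatase gene Ptprr by -0.22 (0 of 4 higher). Zfp516 differed by 0.60 in the family of 129S1/SvImJ, BTBRT T(+) tf/J and LP/J (3 of 3 higher), and Baiap2l1 by -0.20 in the Bagg albino-derived strains (0 of 4 higher), at the lowest value of the table in the other 3 families. Without BTBRT T(+) tf/J 1 gene passed, Pik3r6, and without a filter on low values Baiap2l1 did (limma adjusted p = 0.0037). The differences of Baiap2l1 were 0 with an SD of 0 in the other 3 families, because the values lay at the floor. Its small p rests on that missing spread and is not read as a family difference.

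A greater similarity of response among related strains was not detected. The mean correlation of responses was -0.0061 over 25 pairs within families and -0.0354 over 95 pairs between families, a difference of 0.0292 (permutation test, one-sided p = 0.163). The Mantel correlation of response and expression similarity showed that, over all 30 strains, strains with more similar mean expression had more similar responses (Mantel r = 0.164, permutation p = 0.0018; Spearman rho = 0.180, permutation p = 0.00097; both one-sided). Without P/J and C57BR/cdJ, the 2 strains farthest from the median of expression similarity, r was 0.0933 (permutation p = 0.0409), and it was 0.0259 (p = 0.292) with marker scores as covariates. With the first component of the responses removed the direction reversed, to -0.0881 (p = 0.973). The mean of a strain and its response share the same arrays, so an odd array enters both.

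The size of the response differed between strains. The root mean square of the within-strain difference over genes was 0.452 in P/J, 0.349 in DBA/2J, 0.342 in C58/J, 0.309 in I/LnJ and 0.290 in C57BR/cdJ, against 0.173 in NOR/LtJ, the lowest. In P/J 268 genes were up and 149 down by 2-fold or more. With 1 array per strain and treatment, the response of a strain and a single unusual pool cannot be separated. Over the genes outside the fixed lists, the first component of the 30 responses held 19.9% of their variance and the second 11.7%.

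**Figure D4:**
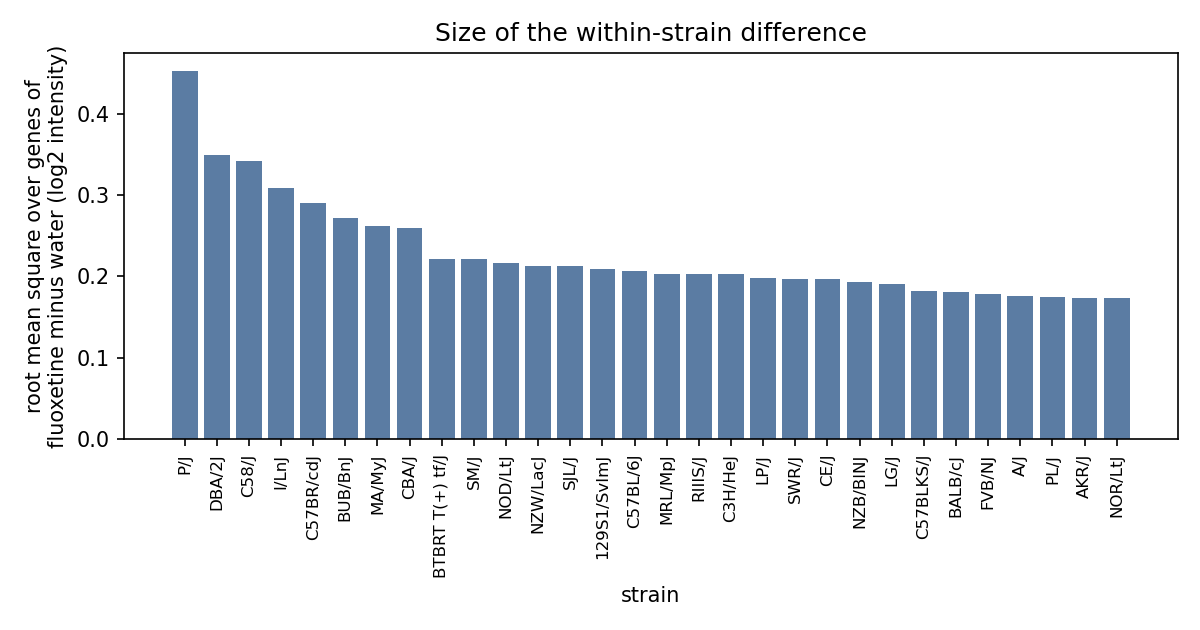
Root mean square over genes of the difference in log2 intensity, fluoxetine minus water, in each of 30 strains, with bars starting at 0. P/J has the largest value, 0.452, and NOR/LtJ the smallest, 0.173.

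Several of the gene groups that shifted moved with this first component over strains, in a family of 11 relations tested by permutation with Benjamini-Hochberg adjustment. The relations with the component were not fixed in advance, and they covered the lists that had passed camera and the astrocyte markers. The mean of the circadian clock genes was lower where the component was higher (r = -0.857, p = 1e-05, the smallest the permutations can give, adjusted 0.00011; rho = -0.466, p = 0.0104, adjusted 0.0381; r = -0.700 without P/J and C58/J, the 2 farthest strains). Heat shock and unfolded protein genes were higher there (r = 0.594, p = 0.0011, adjusted 0.0023; rho = 0.620, p = 0.0004, adjusted 0.0044; r = 0.634 without both). Lysosomal genes had r = 0.674 (p = 0.00015, adjusted 0.00055; rho = 0.349, p = 0.0586, adjusted 0.107; r = 0.482 without both). Cholesterol genes had r = 0.695 (p = 0.00035, adjusted 0.00096), opposite to their fall over all strains, with rho = 0.285 (p = 0.127, adjusted 0.200) and r = 0.365 without both (p = 0.0543), so that the Pearson relation of the mean rested on P/J and C58/J. Oligodendrocyte markers had r = -0.514 (p = 0.0039, adjusted 0.0061; rho = -0.569, p = 0.0013, adjusted 0.0069), and r = -0.316 without both (p = 0.104), so that their relation also rested in part on those strains. Astrocyte markers had r = 0.741 (p = 6e-05, adjusted 0.00033; rho = 0.436, p = 0.0166, adjusted 0.0451; r = 0.396 without both), but this list had not passed its own test, and its 12 members had a median rho of -0.0044 with the component, 6 of them above 0, with Gfap at 0.678. No relation passed for oligodendrocyte precursor markers (r = -0.318, p = 0.0857, adjusted 0.118; rho = -0.272, p = 0.148, adjusted 0.204; r = -0.0378 without both) or endothelial markers (r = -0.0062, p = 0.975, adjusted 0.975; rho = 0.103, p = 0.584, adjusted 0.642; r = -0.0742 without both). The component was computed from genes outside all fixed lists, so no list member entered it, but lists and component come from the same arrays.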

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

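A strain far from the other members of its family was looked for among the genes named in the comparisons, in 69 groups of 4 or 5 strains, and 3 groups held one, where chance flags about 1 in 20 groups. Spata13, which rose over all strains, differed by 0.72 in CBA/J, while the other Bagg albino-derived strains lay between -0.19 and -0.07. Gnb4, which fell over all strains, differed by 0.13 in C3H/HeJ, while the other Bagg albino-derived strains lay between -0.25 and -0.23. Prodh differed by 0.20 in SWR/J, while the other Swiss-derived strains lay between -0.00054 and 0.03. No technical or biological explanation was tested for these 3 values.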

How the results depend on the processing

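The settings without 5 strains, with the first component as a covariate, without C58/J and C57BR/cdJ, and the sign-flip permutation were chosen after the data were seen. For fluoxetine against water in 30 strains (7 genes), 5 of 14 alternatives stayed within 1.5 times that count, from 7 to 10 genes. Of these, 4 held all 7 genes, and array weights, with 10 genes, shared 4 (Tfrc, Nefh, Gnb4 and Sh3d19) and lost Ciart, Zfp945 and Spata13. No replicate block, the mean of all probe sets and marker scores as covariates each gave 0 genes, no filter gave 1, omission of the 5 strains with the largest responses 2 (Fdft1 and Cyp51), every probe set on its own 12 of 25783, the 3' minus 5' covariates 17, the Wilcoxon test 63 and the first component as a covariate 803. Leaving out each strain gave 0 to 21. All 7 genes were among the 17, the 63 and the 803. Dropping the block adds the strain spread to the error by construction; for the rest the cause was not tested. For gene lists, fluoxetine against water (7 lists), the estimated correlation gave 0, fry 1 and the sign-flip permutation 4; the other 11 settings gave 5 to 7 and leaving out a strain 6 to 8, with changes of membership. Marker scores lost the lysosome, oligodendrocyte and oligodendrocyte precursor lists and gained extracellular matrix and deep-layer neurons, the mean of probe sets lost lysosome and endothelium and gained microglia, the first component as a covariate lost endothelium and gained microglia, omission of 5 strains lost circadian clock and lysosome, and the filter at log2 6 lost endothelium. Without the block only the endothelial call was lost, leaving 6. For expression differences between strains, every probe set on its own gave 22053 because more features were tested, while 9 other settings gave 9891 to 10697 and leaving out a strain 10315 to 10645. For response differences between strain families, no filter gave 1, omission of C58/J and C57BR/cdJ gave 2 (Gm10037 and Gm7969), and leaving out a strain 0 to 1. The similarity of response between related strains turned to -0.0163 (p = 0.727) with marker scores and to -0.0199 (p = 0.781) with the first component removed, and was 0.0204 to 0.0564 in the other 8 settings. The Mantel correlation of response and expression similarity was 0.0259 (p = 0.292) with marker scores and -0.0881 (p = 0.973) with the first component removed, and 0.309 over the most variable genes (p = 1e-05, the smallest the permutations can give); the cause was not tested. With marker scores S100a10 turned to -0.0212, Fos to -0.16 and Egr1 to -0.0149, with array weights Fos to -0.0590, and without 5 strains S100a10 to -0.0158, Fos to -0.16 and Egr1 to -0.0012; leaving out a strain moved Fos from -0.0438 to 0.0883 and Egr1 from -0.0160 to 0.0246. None of these 3 genes passed in any setting run. Signal over background limits Slc6a4, Tph2 and other genes at the floor.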

Other observations

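The tests of a neighbouring region and of RNA quality, the fit with the first component as a covariate with its splits, the omission of 5 strains and the genes named as examples of the component were chosen only after the result was seen. The relations of list means with the component and the median rho of the fixed lists were also not among the choices fixed in advance. A set of genes, several of them members of the fixed lists, was much higher in the fluoxetine array than in the water array of a few strains. Rgs13, a regulator of G protein signalling, reached log2 4 in 0 of 30 water arrays, which lay near the floor, and in 10 fluoxetine arrays, the highest of them P/J at 10.21. Nptx2, a pentraxin that gathers glutamate receptors at synapses, was higher by 3.14 in P/J and 2.46 in C58/J, and Ptgs2, the inducible prostaglandin synthase, by 3.10 and 2.24. Bdnf was higher by 2.53 in P/J, 2.06 in C58/J and 1.84 in DBA/2J, while over all strains it was higher in 15 and lower in 15. Gfap, the astrocyte filament protein, was higher by 2.81 in P/J and 3.17 in C58/J, and Fosb, an activity-induced factor, by 2.15 and 1.69. Cd44, an adhesion receptor, was higher by 4.41 in C57BR/cdJ. Each value compares a single pair of pools.

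On the axis of the first component, water arrays lay between -4.41 and 9.31 and fluoxetine arrays between -3.27 and 37.96, with 8 of 30 fluoxetine arrays above the highest water array. The axis was computed from these same differences and its sign was set by their size, so high fluoxetine arrays in strains with large differences are built in. CBA/J is among the 8 at 14.80, but its own water array was the highest at 9.31. Median rho of list members with the component lay above the 95th percentile of random lists for microglial markers (0.382), the catecholamine system (0.365), heat shock genes (0.281), cholesterol synthesis (0.271), strain-variable reference genes (0.269), the glucocorticoid response (0.259), interferon genes (0.232), lysosomal genes (0.192) and immediate early genes (0.168). At the other end, with at most 1.37% of random lists below, stood oligodendrocyte markers (-0.472), clock genes (-0.343), the postsynaptic density (-0.301), oligodendrocyte precursors (-0.292) and synaptic vesicle genes (-0.237). The median of the 2 choroid plexus markers, -0.263, lay within the random range, with 7.98% of random lists below it. Over strains the bootstrap interval of the median included 0 for lysosomal genes (-0.0702 to 0.345), immediate early genes (-0.0694 to 0.377) and synaptic vesicle genes (-0.472 to 0.0079). For cholesterol synthesis 18 of 20 members had a rho above 0 (bootstrap 0.0517 to 0.502), while the rank relation of the mean score of the list did not pass, nor did that of the lysosome list (adjusted 0.200 and 0.107). Ttr, the abundant product of the choroid plexus, differed by -8.35 on the log2 scale in C57BR/cdJ. Its mean over water arrays was 7.51, with the highest water array at 15.09. A fall of that size from the mean would end under the floor, so the water array of C57BR/cdJ lay above the mean. The value therefore reflects a high water pool and is not read as a response to fluoxetine. Whether that pool held choroid plexus was not tested.

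For RNA quality or hybridisation, the 3' minus 5' and spike-in differences held an R squared of 0.160 with the component (bootstrap 0.0602 to 0.495). These controls went with a small share of this pattern, but the interval is wide and they do not cover every processing difference. RNA quality or hybridisation therefore stays open as a source. A hypothesis is neuronal activity or seizures under the drug: late activity-response genes had a median rho of 0.365 (random lists reached 0.205 at their 95th percentile; bootstrap -0.0074 to 0.573), with Npy at 0.641, Sorcs3 at 0.517 and Vgf at 0.489, but Penk at -0.541, Pcsk1 at -0.298 and Homer1 at -0.177 went the other way, and the unrelated strain-variable reference genes passed the same bar (0.269), so that passing it is not specific to activity. Reactive astrocytes may also contribute, with a median rho of 0.372 (95th percentile 0.271; bootstrap 0.0259 to 0.626) over the 4 of 8 genes named in advance that passed the filter (S1pr3, Hspb1, Vim and Cp). Tissue of a neighbouring region stays open too, because 2 of 7 region lists, olfactory bulb and neuroblasts (0.379; bootstrap -0.0412 to 0.608) and meninges (0.206; bootstrap -0.142 to 0.516), lay above the 95th percentile of random lists. In P/J, the strain with the largest component, both lists were lower (-1.43 and -0.36), while in I/LnJ both were higher (1.79 and 0.79).

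The fall of oligodendrocyte markers could come from the share of white matter in the dissection. The scores of oligodendrocyte and deep-layer markers moved together (r = 0.563, permutation p = 0.0013, adjusted 0.0023; rho = 0.425, p = 0.0205, adjusted 0.0451; r = 0.406 without SM/J and MRL/MpJ), but those of oligodendrocyte and striatum markers had r = 0.246 (p = 0.191, adjusted 0.233; rho = -0.127, p = 0.503, adjusted 0.615; r = -0.266 without both), so that depth of the dissection and a change in the cells cannot be told apart. As for a few strains carrying it, without the 5 strains of largest response the mean score was -0.148, against -0.197 over all 30 (bootstrap -0.282 to -0.0221; lower in 15 of 25 strains; permutation p = 0.0383), which leaves open how much of the fall they carry. An effect of fluoxetine on oligodendrocytes remains open as the difference the design names.

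The lower values of clock genes such as Ciart and Dbp may come from tissue taken at another time of day or from a shifted clock. Among the Per genes, Per2 was not lower (0.03, higher in 16 of 30 strains), while Per3 differed by -0.09 and was lower in 17 strains and higher in 13. A shift of phase would raise genes of the opposite phase, and the mean of Arntl, Clock and Npas2 was higher by 0.03 (higher in 20 of 30 strains, permutation p = 0.117), while that of Ciart, Dbp, Per1, Per2, Per3 and Nr1d1 was -0.17 (higher in 5 of 30, permutation p = 3e-05). The latter set was formed from the fall already seen, so its p-value restates that fall and adds no separate support. Over strains the 2 sets had r = 0.125 (p = 0.514, adjusted 0.565; rho = 0.0621, p = 0.745, adjusted 0.745; r = 0.000072 without P/J and DBA/2J). Times of collection were not given in the sources used here, so phase and an effect of the drug on these genes cannot be told apart.

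Other splits of the samples were drawn, 100 with the real one included, by swapping the treatment labels within strains or, for the families, by shuffling the family labels. For the 7 genes between fluoxetine and water, 3 splits had as many (highest other 58), a share under the 0.05 set in advance. This does not exclude chance, since the splits were few and swapped labels gave 32 and 58 genes. Of the other splits, 4 had any gene. A split with 58, several times the real count, points to a structure of the samples, the source of which was not tested. For the 7 gene lists, 19 splits had as many (highest other 12, median 4), so chance is not excluded. For the families, with 0 genes, 100 of 100 splits had as many (highest other 7). With the first component as a covariate, 2 splits, the real one included, reached the 803 genes (highest other 904, median 0). That small share does not exclude chance, because this fit and its splits were chosen after the result was seen. Another split gave 801 and another 472, so the fit can call many genes with swapped labels, which points to a structure of the samples, and the covariate is computed from the same differences.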
